A study of Bifidobacterium breve UCC2003 with 2 samples.

How the data were processed

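Bifidobacterium breve UCC2003, a gut bacterium, was compared with a derivative carrying a mutation in nanR. Both strains were grown without oxygen in modified MRS medium with 0.5% ribose and 0.05% cysteine to an OD600 of 0.5, per the labels' protocols. Total RNA of both strains was hybridised together on 2 two-colour Agilent oligonucleotide arrays with the dyes swapped. The mutant was labelled with Cy5 on array 1 and with Cy3 on array 2. The labels do not say whether the 2 arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Both arrays lay on 1 slide and were read in 1 scan, so no batch could be separated.

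The deposited files hold, for each of 10807 spots, the mean signal and the median local background as scanner intensity, and a log10 ratio of red over green, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.5, while the file headers give version 9.1.1.1. The authors' value table held the same log10 ratio as the scanner files in all 10807 spots, with a largest difference of 0. Its scale, direction (Cy5 over Cy3) and centring are therefore those of the scanner software, and its median was 0 on both arrays. It was used only as an alternative.

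Signals were corrected for background with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 under R 4.3.3. The 544 control spots had weight 0 in loess and were then left out. Spots marked as outliers by the scanner software, 696 on array 1 and 336 on array 2, were also left out, and saturated spots were kept. Log2 ratios were turned to mutant over wild type on both arrays, averaged over the spots of a probe and then over the 3 probes of a gene. Of 1880 target features, 1864 had a probe well above background in either channel on both arrays and were tested. These were 1843 chromosomal locus tags, numbered between Bbr_0001 and Bbr_1926, 20 tRNA features and 1 rRNA feature. The 16 features left out were named for plasmids and an insertion sequence. The RNA spike features and a feature named only CDS were not tested as genes. Of the 1212 genes that passed the test, 59 (4.9%) had probes with ratios on both sides of 0. None of the cluster genes did (0 of 12).

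Each gene was tested with limma's lmFit and eBayes, 2-sided, with Benjamini-Hochberg adjustment over 1864 genes and a threshold of 0.05. The fit left 1 residual degree of freedom per gene. The estimated prior degrees of freedom were infinite, so every gene was tested with one common standard error of 0.149 on the log2 scale. Very small adjusted p-values follow from that common error and not from many arrays. Gene lists were compared with the other genes by camera (preset correlation 0.01, and estimated), with fry beside it. A regularised t-test of the kind the submitters name (Cyber-T) was rebuilt with a window of 101 genes and a prior weight of 10. It is called the methods' t-test here, at the submitters' limits of p under 0.001 and a ratio over 3 or under 0.33. For a gene not well above background in the mutant on both arrays, the fold is a lower bound. The bound sets the wild type's mean against, per array, the higher of the lowest signal well above background and the gene's own signal, after loess and Aquantile.

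The groups, tests, thresholds, gene lists, main alternatives and the rule for named genes were fixed before the data were examined. Of the 19 lists, 2 were ranges of locus tags. They were the sialic acid cluster (Bbr_0160 to Bbr_0172, 12 measured) and its flanks (10 locus tags on each side, 17 measured). The tag range of the cluster was taken from prior knowledge of the strain. The other 17 lists were defined by words in gene descriptions and had 0 members, because the files give no gene descriptions. The gene table supplied with the data belongs to another strain, and 0 of the 1843 locus tags matched it. For that reason the mutated gene nanR was not identified among the tags, its own ratio is not reported here, and no cluster member is given a gene name. The rule asked for every measured cluster member, the 12 genes with the strongest rise and the 12 with the strongest fall, and the 2 extreme members of each list. As locus tags without names say little, only the first 2 of each direction outside the cluster are printed, and the flanks are given as counts and ranges.

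The test was checked on simulated log2 ratios of 1864 genes with known changes. It called 72.7% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1 or 2, with 8 of 1664 unchanged genes called. The noise was drawn independently per gene and array with the common spread of the real fit. These rates therefore hold only where that shared error is right, and they do not test it. In simulated spots with a dim mutant channel, ratios came out compressed. A true log2 change of 1 was measured as 0.48 with offset 50 and as 0.68 with offset 0. At these offsets limma called 0% of genes changed by 1, and 0% and 4.5% of genes changed by 2. The simulated mutant channel was the wild type's level dimmed by one factor per array, so it lacked the wider range of the real one. Its prior degrees of freedom were 1.99 and 3.23, not infinite, so these rates do not carry over to the real test. The methods' t-test with Benjamini-Hochberg adjustment called 6% and 11.9% of genes changed by 1.

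Alternatives covered the background correction, the scanner software's processed signals, the authors' value table, median centring, Aquantile, the filter on dim probes, the median of probes, saturated spots, the variance prior, the unit of the test and the thresholds. Each array was also left out in turn. Equal scaling of the arrays, removal of trends on probe GC content and on locus-tag order, a test with no variance prior, a requirement of the same direction on both arrays, and most alternatives for the flanks were added after seeing the data.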

Results

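Transcript levels of a nanR mutant and of its wild type were compared on 2 dye-swapped arrays, with 1 sample of each strain on each array. Probes covered 1843 chromosomal genes. The number of arrays limits the precision, and every value below is a mean ± SD over n = 2 arrays unless stated otherwise. The channels differed in brightness on both arrays, whichever dye the mutant carried. The median net signal of chromosomal spots, above the negative controls, was 78.1 in the mutant and 859.6 in the wild type on array 1. It was 59.9 and 315.4 on array 2. Spots well above background made up 73.5% and 62.1% in the mutant and 99.8% and 100% in the wild type. The spread of signals also differed. The upper quartile of net signal was 9.69 and 12.2 times the lower quartile in the mutant, but 3.14 and 3.57 times in the wild type. Probes for plasmids and an insertion sequence gave 0 of 87 spots well above background in either strain on either array.

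**Figure D1:**
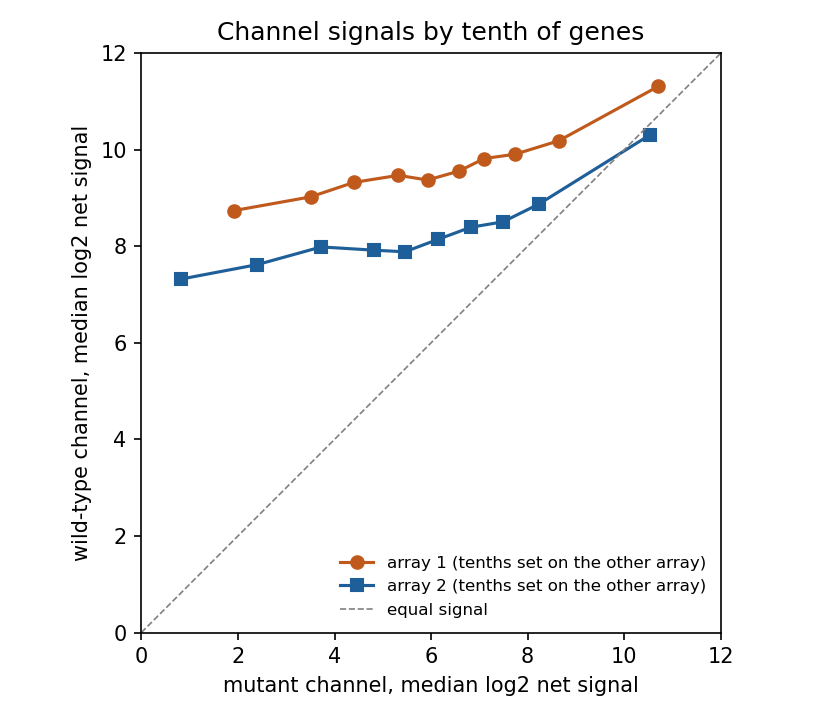
Median log2 net signal of the wild-type channel (vertical axis) against that of the mutant channel (horizontal axis) for 10 equal groups of the 1843 chromosomal genes, with the groups set by the mutant signal on the other array. On array 2 the mutant medians run from 0.82 to 10.53 and the wild-type medians from 7.32 to 10.30.

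The first comparison asked whether the sialic acid cluster, a set of neighbouring genes for the use of sialic acid, had other transcript levels when nanR was mutated. nanR encodes a GntR-type transcriptional repressor, per the series title. In the mutant, 11 of the 12 measured cluster genes were higher than in the wild type, on both arrays, and the median of the 12 was 3.83-fold higher (log2 1.94). The 7 highest ratios of all 1864 genes tested were cluster members. Bbr_0164 rose by 3.14 ± 0.17 on the log2 scale (8.79-fold, limma adjusted p = 2.39e-85), and Bbr_0168 rose by 2.83 ± 0.22 (7.12-fold, limma adjusted p = 3.62e-71). The last tag of the range, Bbr_0172, had a ratio of 0.24 ± 0.08, which did not pass the test (limma adjusted p = 0.14). It passed in 6 alternative settings, at up to 0.71 with the processed signals (limma adjusted p = 0.000418).

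The rises were not even along the cluster. The 4 genes from Bbr_0160 to Bbr_0163 had a median log2 ratio of 1.78. Among them Bbr_0160 stood at 1.93 ± 0.56, Bbr_0161 at 1.75 ± 0.39, Bbr_0162 at 1.36 ± 0.19 and Bbr_0163 at 1.81 ± 0.26. The 7 genes measured from Bbr_0164 to Bbr_0171 had a median of 2.13. This split was not among the comparisons fixed beforehand and was not tested. The ranges of the stretches overlapped, 1.36 to 1.93 against 1.73 to 3.14. Besides the genes named above, Bbr_0165 stood at 2.74 ± 0.21, Bbr_0167 at 1.73 ± 0.33, Bbr_0169 at 2.13 ± 0.11 and Bbr_0171 at 1.95 ± 0.01, while Bbr_0166 was 4.01-fold higher (1.81 and 2.20 on arrays 1 and 2). The order within the cluster depended on loess: with median centring Bbr_0168 was highest at 3.41, Bbr_0164 stood at 2.81, Bbr_0166 at 2.92, Bbr_0167 at 2.91 and Bbr_0169 at 2.90. Adjusted p-values of the 11 genes that passed lay between 2.39e-85 and 5.01e-18 (limma). Their size depended on the infinite prior: with equal scaling of the arrays they lay between 2.51e-07 and 5.58e-06 (limma). Neighbours differed most at the edges of the risen block. The ratio of Bbr_0160 lay 3.20 above that of Bbr_0158, the preceding measured tag (at least 2.40 on either array, standard error 0.211). The ratio of Bbr_0171 lay 1.70 above that of Bbr_0172 (1.76 and 1.64). Inside the block, Bbr_0164 lay 1.32 above Bbr_0163 (1.26 and 1.38).

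**Figure D2:**
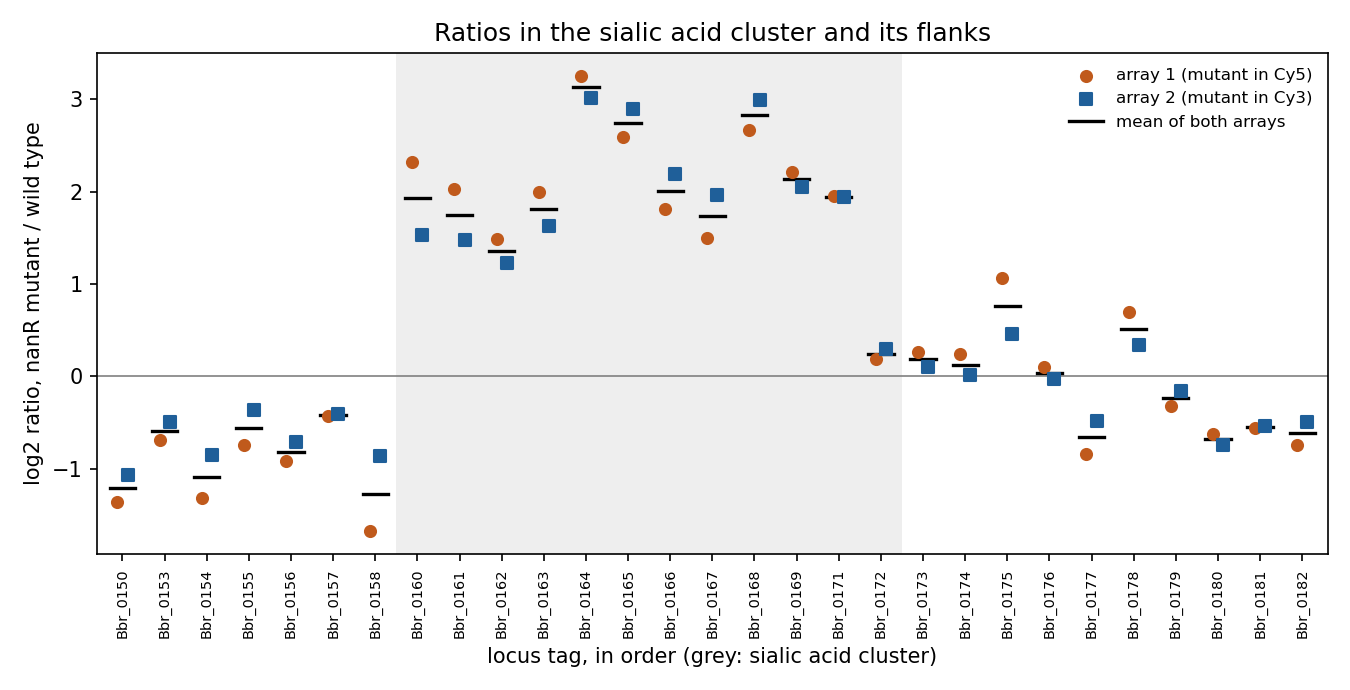
Log2 ratio of nanR mutant over wild type (vertical axis) for the measured locus tags of the sialic acid cluster (grey) and its flanks in tag order, with a point per array and a bar for the mean of both. Of the cluster genes, 11 lie above 1.2 on both arrays, and Bbr_0172 lies at 0.19 and 0.30.

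Against all other genes, the cluster was shifted upwards by camera (adjusted p = 1.04e-21 over both lists, preset correlation). With an estimated correlation the call was lost (adjusted p = 0.123 with an estimated correlation, which leaves the test 1 residual degree of freedom). The fry test in limma looks at the set alone and found that its genes moved on balance one way, with a fry p of 0.0107. Adjusted over the list alone, 11 of the 12 genes passed, as over all genes tested. The series title names the sialic acid cluster, and its tag range came from prior knowledge of the strain, so its direction is not independent evidence.

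Most flanking genes that passed the test went the other way. On the low-number side, all 7 measured genes from Bbr_0150 to Bbr_0158 were lower in the mutant, with log2 ratios between -1.27 and -0.42 and a median of -0.82 (limma, adjusted p under the threshold for each). With the median of probes, or with the tag-order trend removed, 5 of the 7 passed. On the high-number side, from Bbr_0173 to Bbr_0182, 2 of 10 genes were higher, 4 were lower and 4 did not pass, with a median of -0.10. Over both sides, 13 of 17 passed, adjusted over the list alone and over all genes. The flanks as a list were shifted downwards by camera (median log2 -0.55, adjusted p = 0.0137). That call was lost with an estimated correlation (adjusted p = 0.272 with an estimated correlation), with the processed signals (median -0.89, adjusted p = 0.0578) and after removal of the trend along the locus tags (median -0.34, adjusted p = 0.24). The fry p was 0.0705.

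The second comparison covered the whole gene set. Outside the cluster, the strongest falls exceeded the strongest rises. Bbr_0691 fell by 3.63 ± 0.01 on the log2 scale in the mutant (12.3-fold, limma adjusted p = 1.96e-110), and the measured tag before it stood at -3.05. Bbr_1847 fell by 3.08 ± 0.02 (8.45-fold, limma adjusted p = 1.05e-82), while the tags on either side of it stood at 0.21 and 0.10. Their normalised signals were 3840 and 2470 in the wild type and 311 and 293 in the mutant. Among rises, Bbr_0610 reached 1.86 ± 0.20 (3.62-fold, limma adjusted p = 4.29e-32) and Bbr_1425 reached 1.79 ± 0.11 (3.46-fold, limma adjusted p = 5.34e-30). The 12 strongest rises outside the cluster lay between 2.97-fold and 3.62-fold, and the 12 strongest falls between 3.02-fold and 12.3-fold.

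In all, 33 genes differed by more than 3-fold in mean ratio with the same direction on both arrays, 20 higher and 13 lower in the mutant. This count depended on the processing: it was 113 with offset 0 and 286 with the processed signals (73 higher, 213 lower), and 56 or 20 on array 1 or 2 alone. Of the 20 higher genes, 10 belonged to the cluster. The methods' t-test at the submitters' limits gave 33 genes, 20 higher and 13 lower. It used the same mean ratios, and 725 genes had p under 0.001 without the fold limit, so that limit set the count. After Benjamini-Hochberg adjustment alone the methods' t-test gave 1240. By limma, 1212 of 1864 genes (65%) passed, 593 higher and 619 lower in the mutant. As measured with offset 50, 991 of the 1212 (81.8%) were 2-fold or less, and 221 were over 2-fold. Simulated spots with a dim mutant channel gave compressed folds at this setting, with a log2 change of 1 measured as 0.48. The simulated mutant channel lacked the wide range of the real one, so the size of any compression in the real folds is not known. The direction was the same on both arrays for 1209 of the 1212, and for 89.9% of all genes tested. Genes were called on the mean of these same arrays, so that agreement is largely set by the selection. Of the 619 lower genes, 168 were not well above background in the mutant on both arrays, so their folds are bounds. The bound was above 1 for 152 of them, with a median of at least 1.38-fold lower and a highest value of at least 3.18-fold lower. The other 16 have no fold. The bounds apply to transcripts only if the wild-type signal of these genes is transcript, and genomic DNA in that channel stays open, as described below. When probes had to be well above background in both channels, 892 of 1456 genes passed, 577 higher and 315 lower. This filter takes out mainly genes low in the mutant, so it favours rises. With no variance prior, 0 genes passed after adjustment and 316 had an unadjusted p under 0.05.

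**Figure D3:**
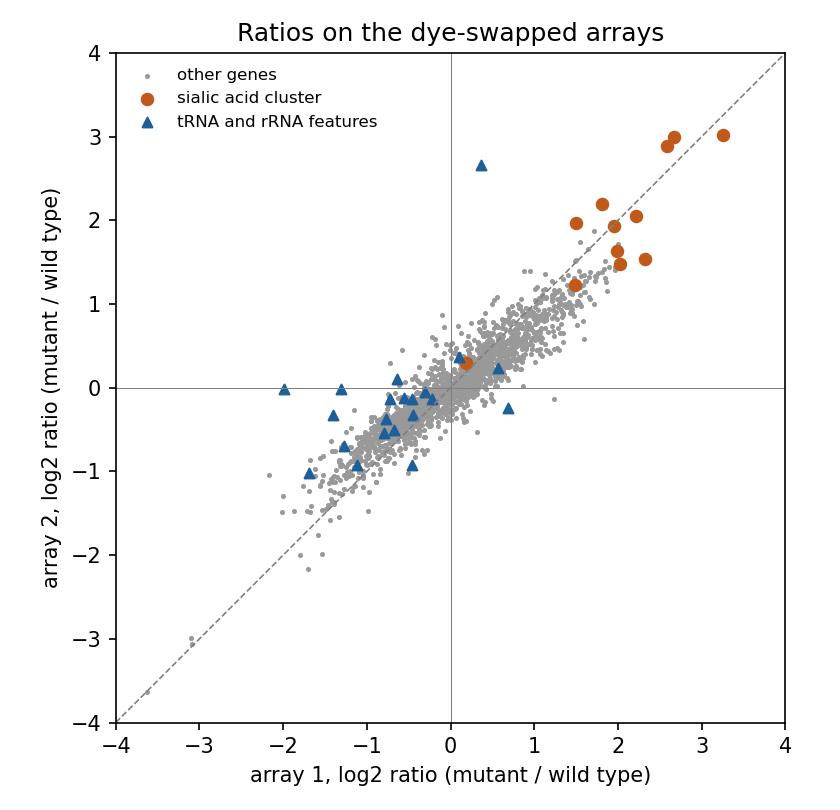
Log2 ratio of nanR mutant over wild type on array 2 (vertical axis) against array 1 (horizontal axis), a point per gene or RNA feature, with equal values on the dashed line. Most features lie along that line (correlation across genes 0.93), with cluster members at the upper right and a few RNA features away from it.

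Ratios on the 2 arrays correlated at 0.927 across 1864 genes, which are not independent replicates. Their standard deviation across genes was 0.75 on array 1 and 0.60 on array 2. A few RNA features differed widely between the arrays. The rRNA16s feature stood at 0.36 and 2.67 on arrays 1 and 2, and tRNA-Asn at -1.99 and -0.01. Both passed in limma, where every gene shared one error, and by the methods' t-test after adjustment, but with robust eBayes in limma their adjusted p-values were 0.481 and 0.561. Of the 20 tRNA features, which report transfer RNAs used in protein synthesis, 13 were lower in the mutant, 1 was higher and 6 did not pass, with a median log2 ratio of -0.50. That median rested more on array 1, where it was -0.66, than on array 2, where it was -0.19, and 4 of the 13 falls were within 0.2 of 0 on array 2. Examples picked after their values were seen were tRNA-Asp at -1.36 ± 0.48 and tRNA-Thr at -1.02 ± 0.14. In 13 alternative settings that kept both arrays, the tRNA median lay between -0.85 and -0.43.

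Ratios followed the order of the locus tags. The order was divided into 10 equal parts. In the part with the lowest numbers, the median log2 ratio was -0.47, with 112 of 182 genes lower in the mutant and 31 higher. In the part with the highest numbers it was -0.37, with 102 of 184 lower and 32 higher. The medians of parts 4 to 7 lay between 0.17 and 0.24. In part 5, 83 of 186 genes were higher and 29 lower. From either end of the order to its middle the ratio rose by 0.73 on the log2 scale (95% bootstrap interval 0.53 to 0.92, blocks of 20 neighbouring genes). The rise was 0.83 on array 1 and 0.63 on array 2. In 13 alternative settings that kept both arrays and the trend, it lay between 0.67 and 1.20, highest with the processed signals. This regression was chosen after the trend was seen.

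**Figure D4:**
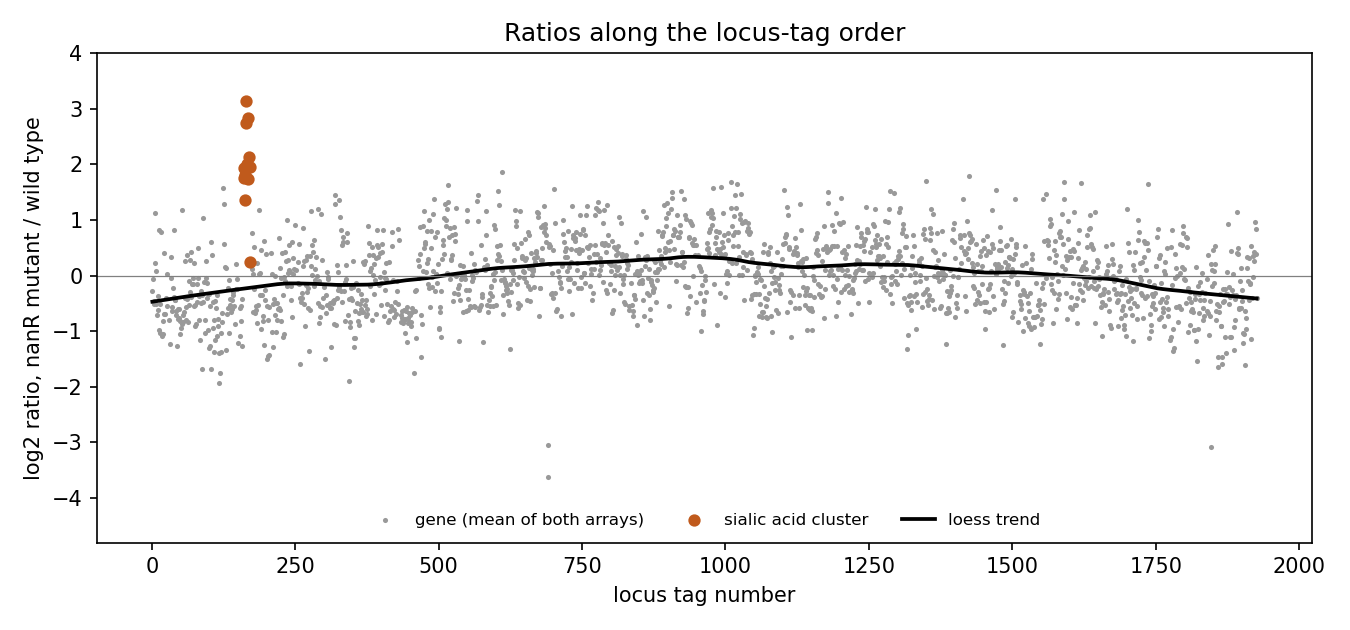
Log2 ratio of nanR mutant over wild type (vertical axis, mean of both arrays) against locus tag number (horizontal axis), a point per chromosomal gene, with a loess trend. The trend is lowest at both ends, and the cluster stands above it with 11 genes between 1.36 and 3.14.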

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

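The features kept out of the comparisons were looked at only after the data were seen. A feature named CDS, which the files tie to no gene, was well above background in 1 channel or both in 12 of 12 spots over both arrays. Its log2 ratio of mutant over wild type was 0.35 on array 1 and 0.67 on array 2 (mean 0.51 ± 0.23 SD, n = 2), with no test. Of the 7 RNA spike features, 6 had 0 spots well above background, and RNASPIKE8 had 1 of 10.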

How the results depend on the processing

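Equal scaling, both trend removals, the test with no variance prior, the same-direction requirement and most settings for the flanks were chosen after the data were seen. The 16 named genes kept their direction in all 256 values over 16 settings. In 250 of the values the genes also kept their side of the threshold or stayed within the arrays' spread, and in the other 6 Bbr_0172 passed. The size of the p-values was less stable. With equal scaling the prior degrees of freedom were 10.5, and the adjusted p of Bbr_0691 was 3.03e-07 (limma). That of the cluster was then 1.76e-07 (camera). Aquantile and leaving out saturated spots gave the same values as the main setting, so they add no support. The cluster median stayed between 1.85 and 2.43, and its call was lost only with an estimated correlation (1.94, adjusted p = 0.123). It was 1.95 to 2.01 when an array was left out. The flanks lost their call with the processed signals (-0.89, adjusted p = 0.0578), the tag-order trend removed (-0.34, adjusted p = 0.24) and an estimated correlation (-0.55, adjusted p = 0.272), over a range of adjusted p from 0.00537 to 0.272. They stood at -0.62 to -0.48 with an array left out.

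The count of 1212 genes became 33 by the methods' t-test at the submitters' limits, 33 with a 3-fold limit added, 3170 with 5384 probes tested instead of genes, and 0 with no variance prior. It lay between 892 and 1358 in all other settings. The count of 33 genes over 3-fold became 62 with plain background subtraction, 113 with offset 0, 129 with median centring, 286 with the processed signals (73 higher, 213 lower) and 287 with the authors' value table (73 higher, 214 lower). It was 20 to 56 with an array left out. In simulated spots, offset 0 compressed dim ratios less than offset 50. The cause was not tested for the other settings. Saturated spots and Aquantile moved nothing. Requiring signal in both channels changed the balance of calls to 577 higher and 315 lower. That balance follows from the genes the filter removed, since all 892 calls were also main calls in the same direction. The filter kept 1456 of 1864 genes. Those removed included the 214 genes dim in the mutant on both arrays, and others besides, while 0 genes were dim in the wild type. The median log2 ratio of all genes the filter kept was 0.17. The dim mutant channel left 168 of the falls as bounds. The main test was already paired, since each ratio sets both strains of 1 array against each other.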

Other observations

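The tests of adjacent genes, of wild-type signal against mutant signal, and of bright and dim genes under other settings were chosen only after the result was seen. Neighbouring genes moved together beyond the trend along the chromosome. With a smooth trend along the locus tags removed, the log2 ratios of 1778 pairs of adjacent tags correlated at 0.40. In 1000 shuffles of the genes, the upper limit of the central 95% of values was 0.05 (permutation p = 0.001, the smallest they can give). Genes are not independent replicates, and probes of adjacent genes were not tested for shared sequence.

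The first pattern is the fall of ratios towards both ends of the tag order. With probe GC content in the regression, 0.991 of the slope was left, which argues against it as the cause. With signal level the share was 1.06. Loess had already removed the trend of the ratio on signal, so this share cannot decide on signal level. A small share of genomic DNA in the signal would weaken the slope in bright genes. With genes in 3 equal groups by signal, the slope in the brightest over that in the dimmest was 1.63 (95% interval 0.96 to 2.47). It was 1.12 with offset 0 (0.68 to 1.67) and 0.806 with the processed signals (0.50 to 1.18). These values argue against such a small share as the whole cause. They cannot decide on genomic DNA that makes up most of the wild-type signal, where bright genes need not lose the slope. Genomic DNA in the wild-type channel would give a fall of wild-type signal from the ends to the middle in genes dim in the mutant. That was seen: the log2 slope in 212 such genes was -0.733 on both arrays (95% intervals -1.10 to -0.41 and -1.09 to -0.42). Over all 1843 genes the wild-type slopes were -0.803 and -0.784. The mutant-channel slopes were 0.31 (-0.48 to 1.13) and 0.36 (-0.47 to 1.22). Genomic DNA in the wild-type channel therefore stays open. The slope of the log2 ratio was 0.753 in the lower-numbered part of the order and 0.704 in the other. These slopes restate the fall at both ends, which was seen first, so they do not tell causes apart. A difference in gene copy number along the replicating chromosome may contribute and stays open, as does an untested effect of nanR.

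The second pattern is that 65% of genes passed the test. The calls were not confined to genes dim in the mutant: genes bright in both channels passed 1.08 times as often as the others (67.7% against 62.7%). All genes shared one error and one loess fit per array. A channel difference that also shifts bright genes is therefore not excluded by this comparison. Removing the trend on probe GC content left 0.957 of the calls, and removing that along the tags left 0.802, which argues against either as the whole cause. With genes in 10 equal groups by mutant signal, from group 5 to group 7, the wild-type signal rose by at most 0.379 of the rise in the mutant signal. From group 3 to group 7 the share was lower, 0.132 on array 2 and 0.183 on array 1. Group 3 was near background in the mutant, with net signals of 13.2 and 21.1, and the narrower range was chosen for that reason. Plasmid probes stayed at background, but they do not report the chromosomal genes, so this does not decide on chromosomal DNA. The share of 0.379 does not decide whether genomic DNA in the wild-type channel contributed, and the lower shares go with it. Widespread effects of the nanR mutation stay open as untested.

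The third pattern is the fall of all 7 measured genes on the low-number side of the cluster. With the tag-order trend removed, their median log2 ratio went from -0.82 to -0.576, and 5 of the 7 passed the test. That lay inside the central 95% of medians of 1837 windows of 7 consecutive genes (-0.70 to 0.72). The fall may thus be part of the variation seen along the whole chromosome, and an effect tied to the neighbouring cluster was not tested separately.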
